A study of Mus musculus with 6 samples.

How the data were processed

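Female BALB/c mice, 8 weeks old at inoculation, received 50 µL of 4T1 cells at 2000000 per mL in a mammary fat pad, per the labels. Nanoparticles (1 mg) or saline were injected intravenously every 3 days from day 1 to day 13, and lungs were taken on day 14. Tissue was digested for 30 min, lung cells of the treated arm were sorted by CD45 and nanoparticle signal, and libraries were made with the 10x fixed RNA (Flex) chemistry, in which pairs of probes ligate on each transcript. The target depth was 25000 reads per cell, per the series' design text. The labels name no sort for the control lung or the tumours, do not say how many mice went into a library, and do not say what the probe barcodes within a library stand for. The NP+ library held 3 probe barcodes, the NP- library 2 and each other library 1.

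Each deposited matrix holds raw UMI counts per gene and cell barcode for 19059 probed genes. Cell Ranger and the mouse probe set are named per the file headers, and Cell Ranger 8.8.0 and 9.0.1 with GRCm38 (mm10) per the submitters' processing notes. How barcodes were called as cells and whether they were filtered further is not given in the sources used here. The total was 212980495 UMIs in the NP+ gate, 198545332 in the NP- gate, 29418356 in the CD45- gate, 46043680 in control lung, 106793340 in the NP tumour and 168378471 in the saline tumour, with medians of 2231, 2366, 1837, 1225, 2120 and 2217 genes per barcode. Counts for all cells of a class were summed before any ratio was taken, so that deep classes have narrow intervals and small classes wide ones. Some list and marker genes were not analysed here, among them Cx3cr1, Ly6c2, Mx1, Psme2, Ear1, Ear2, Gapdh and Nos3. Some other genes are not reported here.

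Cells were kept with at least 300 UMIs, at least 200 genes and at most 20% mitochondrial UMIs. The mitochondrial limit removed 46, 7, 6, 12, 217 and 267 barcodes in the order above, and the other limits removed none. Scrublet, run per library in scanpy 1.11.5 with its automatic threshold, marked 4.32%, 4.67%, 1.67%, 5.26%, 0.809% and 0.0375% of cells as doublets, and these were removed. In the saline tumour it marked 6 of 15982 cells and so did not work there, and an alternative with the NP tumour's threshold was added after this was seen. The kept cells numbered 19345, 19333, 7136, 13213, 9681 and 15976.

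The 4 lung libraries were clustered together and the 2 tumour libraries together, without batch integration, on the log of counts per 10000 with 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1.0 (leidenalg 0.10.2, igraph 0.11.9, seed 0). Lung gave 38 clusters, split further where they mixed classes into 60, of which 46 were named in 20 classes. Tumour gave 30 clusters, split into 41, of which 29 were named in 16 classes. Markers of 32 classes were fixed before the data were examined, as were the gene lists, the main comparisons, the size rule and the alternatives listed last. A name needed at least 3 detected markers of its class at 10 CPM or more, and leading genes that did not go against it.

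Several naming choices were made after the clusters were seen, in several passes. These were the thresholds of the marker score (at least 0.8 for the best class, a runner-up below 0.75 of the best, and at least 2.5 before a cluster could count as erythroid or platelet, since free RNA of lysed red cells and platelets is no second identity), an exception to the runner-up limit among T cells, NK cells and ILC2, and 11 clusters left unnamed by hand. Clusters split between macrophages and classical monocytes were not clustered again. The 11 mixed markers of different classes, were shallow, or were led by genes of cells with no class here, such as liver, early myeloid progenitors and normal mammary epithelium. The hand-set clusters held 2.71%, 1.10%, 3.83%, 2.51%, 7.77% and 10.15% of kept cells in the order above, and clusters left unnamed by the rules 0.817%, 1.01%, 0.210%, 1.33%, 2.23% and 2.25%. The check that a cluster's 10 leading genes hold no more markers of another class than of its own was also changed, from fold over all other cells to fold over clusters of other classes. By fold over all other cells, clusters c3 and c7 of lung neutrophils, c6 of tumour carcinoma cells and c11 of tumour macrophages held more markers of another class. Comparisons within single clusters, not c3 or c7 among them, were also added after the clusters were seen.

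Within a class, UMIs were summed per library and scaled by that sum to CPM, and a class was compared where both libraries held at least 50 of its cells. There is 1 library per group, so no test was run and no p-value is given. A gene was called higher or lower, the size rule, if its CPM ratio was at least 2 or at most 0.5, the exact conditional binomial 95% interval of the ratio excluded 1, and the sums held at least 20 UMIs together. Genes named were the 8 highest and 8 lowest by the interval bound nearest 1 among those that reached 50 CPM in a library, leaving aside markers of other classes, which are given as a count with the leading ones. For each of 31 fixed gene lists the members higher and lower were counted, with the 2 highest and 2 lowest looked up. The list's median log2 ratio of (CPM + 1) was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. CPM carry exact Poisson intervals and shares of cells exact Clopper-Pearson intervals, all of 95% and covering counting error only. A count of 0 cells was taken to allow up to 3.

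There were 21 main class comparisons, and 2 of nonclassical monocytes were added after class sizes were seen. The lists reported beyond MHC class I, MHC class II, type I interferon and interferon gamma were picked after their medians were seen, as were the genes given for the C1qa-rich macrophage cluster and the level of single genes across classes in the closing part. The comparison code was tested on simulated data with 200 genes changed. For lung macrophages, NP+ against NP- (11139 genes run), it called 0%, 98%, 100% and 100% of genes changed by 1.5, 2.5, 4 and 8-fold and 0.229% of unchanged genes. For lung macrophages against control lung (10727 genes run) it called 4%, 96%, 98% and 100%, and 0.551%. For tumour fibroblasts (11685 genes run) it called 2%, 94%, 100% and 100%, and 0.427%. These rates apply to simulated counts and are not rates of false or missed calls between real libraries. In macrophages, NP+ against NP-, the simulation called 25 unchanged genes. Between real probe barcodes of the same gate, each holding part of those macrophages, 91 to 136 genes met the size rule.

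Alternatives were no filter on cells, at least 1000 UMIs per cell, doublets kept, Leiden resolutions 0.5 and 2.0, median-of-ratios size factors, each cell weighted equally, and at least 100 UMIs over both libraries per gene. At other resolutions a cluster took the class most of its cells had at 1.0. Analyses ran in python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and figures were drawn with matplotlib 3.10.9.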

Results

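Single-cell transcriptomes were measured in lungs and primary tumours of female BALB/c mice with orthotopic tumours of 4T1 cells, a mouse mammary carcinoma line that spreads to lung, here carrying tdTomato and luciferase. Mice received intravenous nanoparticles (NP) or saline, and the series title concerns antigen presentation by monocyte-derived dendritic cells, metastasis and immunosuppression in the metastatic niche. The 6 libraries were 3 sorted fractions of NP-treated lung (CD45+ cells with NP signal, the NP+ gate, CD45+ cells without it, the NP- gate, and CD45- cells), 1 library of saline-treated lung (control lung), 1 of NP-treated tumour and 1 of saline-treated tumour. The deposited matrices held 20265, 20287, 7263, 13958, 9977 and 16249 barcodes in that order, with medians of 7339, 6552, 3326, 2260, 3651 and 3770 UMIs per barcode. Classes were named from marker genes, so each name stands for cells with the transcriptome of that type (macrophage-like cells and so on). With 1 library per group no difference has a replicate check, and all intervals are 95% intervals that cover counting error only.

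The NP+ gate of treated lung held more nonclassical monocytes and alveolar macrophages and fewer lymphocytes than the NP- gate. Nonclassical monocytes, the patrolling blood monocytes, made up 20.7% of kept cells in the NP+ gate (Clopper-Pearson interval 20.1 to 21.2%, 3998 of 19345 cells) and 4.68% in the NP- gate (4.38 to 4.98%, 904 of 19333 cells). Alveolar macrophages, the resident macrophages of the airspace, made up 7.78% (7.41 to 8.17%) and 0.471% (0.379 to 0.578%). Other macrophages were 8.77% (8.37 to 9.17%) in the NP+ gate and 6.09% (5.76 to 6.44%) in the NP- gate. Neutrophils were the most numerous class of both gates, with 53.9% (53.2 to 54.6%) and 48.0% (47.3 to 48.7%).

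Classical monocytes, the inflammatory blood monocytes, showed the opposite order, with 3.003% (2.77 to 3.25%) of the NP+ gate and 9.08% (8.68 to 9.49%) of the NP- gate. B cells made up 0.393% (0.310 to 0.492%) of the NP+ gate and 10.8% (10.4 to 11.25%) of the NP- gate, T cells 1.17% (1.02 to 1.33%) and 9.55% (9.14 to 9.98%), and NK cells 0.403% (0.319 to 0.503%) and 7.75% (7.38 to 8.13%). Conventional type 2 or monocyte-derived dendritic cells, a pooled class, numbered 6 and 22 cells, with 15 in control lung, and were not compared. The series title concerns monocyte-derived dendritic cells. The markers did not separate these from conventional ones, and some may be named monocytes or macrophages here, so the counts do not give their number. The sort itself sets these shares, and how many lung cells entered each gate is not given in the sources used here. Over the 3 probe barcodes of the NP+ gate, neutrophils held 52.3 to 55.4% and nonclassical monocytes 19.97 to 22.1% of cells, whereas T cells held 2.84% in 1 of them and 0.508% and 0.390% in the others.

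**Figure D1:**
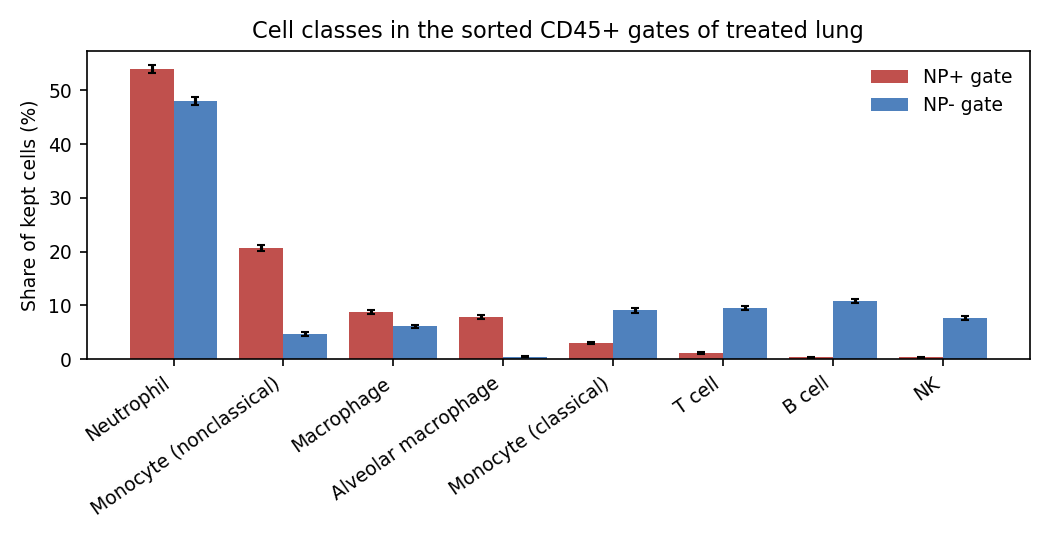
Share of kept cells (%) of 8 cell classes in the NP+ gate and the NP- gate of treated lung, 1 library each; error bars are 95% Clopper-Pearson intervals and cover counting error only. Nonclassical monocytes reached 20.7% against 4.68% and B cells 0.393% against 10.8%.

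Macrophages of the NP+ and NP- gates were compared to find what set apart those that held particles. Gpnmb (ENSMUSG00000029816), a lysosomal membrane glycoprotein, was 25.4-fold higher in the NP+ gate (interval 20.8 to 31.2), the secreted phospholipase Pla2g2d 14.2-fold (11.8 to 17.3) and the fatty acid binding protein Fabp5 6.42-fold (5.74 to 7.19). The endosomal tetraspanin Cd63 was 3.66-fold higher (3.39 to 3.94), Plxna1 3.73-fold, Vat1 3.38-fold, the receptor Slamf7 3.14-fold and the acid phosphatase Acp5 2.80-fold. Retnla (ENSMUSG00000061100), a secreted product of alternatively activated macrophages, showed 3 UMIs in the NP+ gate and 3506 in the NP- gate, a ratio of 0.000600 (0.000124 to 0.00176). In all, 189 genes were higher and 243 lower by the size rule among 11147 measured, and 96 and 56 with at least 100 UMIs per gene. A further 4 lower genes were markers of other cell types and were set aside: the neutrophil genes Retnlg (2.58-fold), Ngp (2.46-fold) and Mmp9 (2.20-fold), and Lcn2 (2.22-fold), a carcinoma marker that neutrophils also express.

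In these macrophages lipid uptake and efflux genes had a median log2 ratio of 0.62, with 4 of 15 measured members higher, led by Fabp5 and Fabp4, and none lower. Nrf2 and iron genes had a median of 0.70, with 3 of 14 higher, among them the iron exporter Slc40a1 (2.43-fold) and the quinone reductase Nqo1 (6.54-fold). Lysosomal genes had a median of 0.22 with 4 of 25 higher. These 3 medians lay at percentile 100 of matched random lists. The immunosuppressive list had a median of 0.18 (percentile 100) with 2 of 18 higher, Il10 at 3.15-fold and Pdcd1lg2, which encodes PD-L2, at 2.05-fold. The monocyte-derived dendritic cell list had a median of -0.18 (percentile 0.450) with 4 of 13 lower. Its lectin Mgl2 stood at 1.95 against 19.4 CPM and Cd209a at 1 against 73 UMIs, a ratio of 0.00961 (0.00024 to 0.0552), while Itgax was at 198 against 124 CPM. With at least 100 UMIs per gene that median was 0.02. No member passed the size rule among the MHC class II (median 0.07, 13 measured), MHC class I (0.01, 14), type I interferon (-0.09, 15) and interferon gamma lists (-0.08, 13). At Leiden resolution 0.5 macrophages merged with classical monocytes, and this comparison has no value there.

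A finer cluster rich in the complement gene C1qa (603 CPM in its NP+ cells and 1410 CPM in its NP- cells) held 21.8% of the macrophages of the NP+ gate (369 of 1696, interval 19.8 to 23.8%) and 9.25% of those of the NP- gate (109 of 1178, 7.66 to 11.05%). Within that cluster alone Gpnmb stood at 463 CPM (447 to 479) in the NP+ gate and 37.0 CPM (29.1 to 46.5) in the NP- gate, Pla2g2d at 313 and 56.6 CPM, and Retnla at 0 and 1755 CPM. In the other 1327 and 1069 macrophages Gpnmb was at 9.22 and 1.29 CPM, Pla2g2d at 1.38 and 0.143 CPM and Fabp5 at 10.2 and 9.20 CPM, so this cluster carried most of these transcripts in the NP+ gate. Of the Retnla UMIs of the NP- gate 3505 lay in its 109 cells. The MHC class II chain H2-Ab1 was at 5326 and 5344 CPM there. This cluster was singled out after its values were seen.

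**Figure D2:**
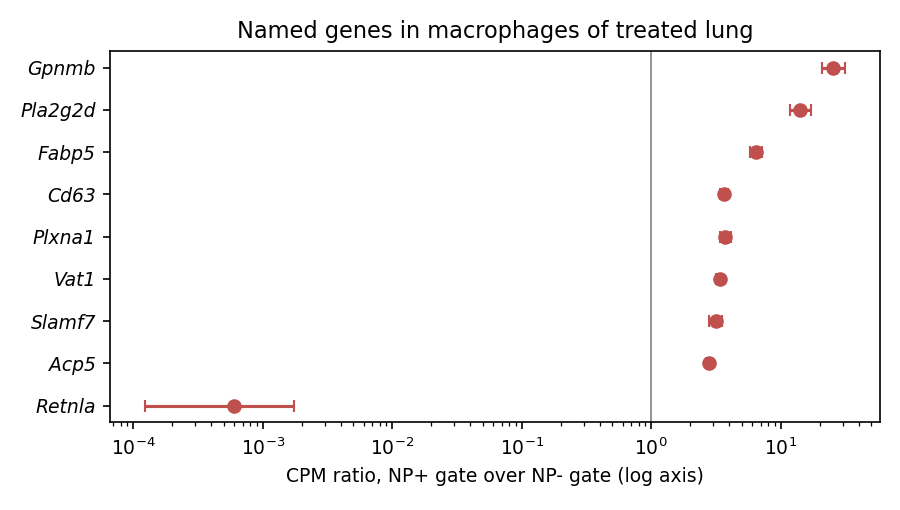
CPM ratio of the NP+ gate over the NP- gate (log axis) for the 9 genes named by the fixed rule in lung macrophages, 1696 and 1178 cells; points are ratios of summed counts and bars exact 95% counting intervals. Gpnmb lay at 25.4-fold and Retnla at a ratio of 0.000600.

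Nonclassical monocytes had 154 genes higher and 153 lower in the NP+ gate than in the NP- gate among 11035 measured, and 59 and 34 with at least 100 UMIs per gene. Cd300e (ENSMUSG00000048498), an activating receptor, was 2.03-fold higher (1.95 to 2.12). The chemokine Ccl5, a leading gene of NK cells here, was 2.38-fold lower. Their lysosome list had a median of 0.13 with 3 of 25 higher, and scavenger receptors 0.18 with 2 of 17 higher (Mrc1 and Marco). Their MHC class II list had a median of -0.19 (percentile 0.00) with no member past the size rule, their type I interferon list -0.11, interferon gamma -0.03 and MHC class I 0.02.

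Classical monocytes had 71 genes higher and 202 lower of 10761, and 11 and 56 with at least 100 UMIs per gene. At Leiden resolution 0.5, where they hold the macrophages too, the counts were 328 and 320. The neutrophil markers Retnlg (2.38-fold lower) and Ngp (2.002-fold lower) were set aside, which left no gene to name by size. Scavenger receptors had 5 of 17 higher and 1 lower (median 0.18), with the lipid receptor Cd36 2.23-fold and the integrin Itgax 2.24-fold higher. Lipid uptake had 2 of 14 higher (median 0.20), led by the nuclear receptor Pparg at 2.92-fold. The monocyte-derived dendritic cell list had 1 higher and 2 lower of 12 (median -0.06), the growth factor receptor Flt3 3.07-fold lower. Among 13 MHC class II genes H2-Ob was 4.95-fold lower (median 0.10), and MHC class I, type I and interferon gamma medians were 0.02, 0.19 and -0.06, the type I median being -0.02 at Leiden resolution 0.5.

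Alveolar macrophages, 1506 and 91 cells, had 79 genes higher and 120 lower of 10846 in the NP+ gate, and 73 and 46 with at least 100 UMIs per gene. The semaphorin Sema4d was 2.01-fold higher, and Ifitm6 2.56-fold and the chemokine Ccl4 2.19-fold lower, while the markers Ngp (2.497-fold lower) and Lcn2 (2.35-fold lower) were set aside. Their cholesterol synthesis list had a median of 0.36 (percentile 100) with 1 of 14 higher, the sterol desaturase Sc5d at 2.08-fold. Their interferon gamma list had a median of -0.24 (percentile 0.0300) with none past the size rule, and 0.07 with doublets kept. MHC class II had 1 of 12 lower (median -0.09, H2-DMb1 2.02-fold) and type I interferon 1 of 15 lower (0.04, Oasl1 3.58-fold), and the MHC class I median was -0.06.

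Neutrophils of the NP+ gate had 406 genes higher and 474 lower of 11396, and 151 and 219 with at least 100 UMIs per gene. The C-type lectin receptor Clec4n (ENSMUSG00000023349) was 2.41-fold higher (2.32 to 2.504), while the immunoglobulin chains Igkc and Ighm were 22.5-fold and 3.43-fold lower and Ccl5 5.57-fold lower. The NK cell marker Gzma was 19.9-fold lower and set aside. Granule genes of immature neutrophils had a median of -0.59 (percentile 0.00) with 3 of 13 lower, Ms4a3 at 3.39-fold and Fcnb at 2.56-fold, and chemokine receptors -0.36 with 3 of 11 lower, led by the lymphocyte receptors Ccr6 and Ccr7. Lysosome (median 0.31, 4 of 25 higher) and lipid genes (median 0.42, 6 of 15 higher) were led by Atp6v0d2, Gpnmb, Lpl and Pparg. MHC class I, type I interferon and interferon gamma genes had medians of 0.26, 0.26 and 0.25 without a member past the size rule, and MHC class II 0.13 with 3 of 13 lower.

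RNA of other cells moved with the neutrophil, monocyte and macrophage lists. Alveolar macrophages, 7.78% of the NP+ gate and 0.471% of the NP- gate, held Atp6v0d2 at 720.7 and 637.9 CPM, Lpl at 1593 and 1580 CPM, Gpnmb at 344.9 and 387.2 CPM and Pparg at 255.8 and 266.0 CPM in the 2 gates. They also held Mrc1 at 2115 and 1998 CPM and Marco at 46.53 and 79.22 CPM, the receptors that were higher in nonclassical monocytes of the NP+ gate, and Cd36 at 258.1 and 267.2 CPM and Itgax at 696.4 and 621.3 CPM, which like Pparg were higher in classical monocytes of that gate. Their marker Plet1, at 2259 and 2309 CPM in alveolar macrophages, was at 8.63 against 1.35 CPM in the other macrophages. NK cells, 0.403% of the NP+ gate and 7.75% of the NP- gate, had Gzma and Ccl5 among their leading genes. Ccl5 was 2.38-fold lower in nonclassical monocytes and 5.57-fold lower in neutrophils of the NP+ gate, and RNA of NK cells was not separated from this. Most neutrophils lay in clusters c3, c2 and c7 in the NP+ gate and in c2, c5 and c6 in the NP- gate, and within c6 alone the MHC class I, type I and interferon gamma medians of neutrophils were 0.05, 0.08 and -0.02. Within c12 alone the MHC class I median was 0.08 and the interferon gamma median 0.09. Clusters c2 and c3 had interferon-inducible genes among their leading genes, so a comparison within 1 cluster holds part of such a difference fixed.

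In 8 cell classes set against control lung, interferon gamma inducible genes had a median above 0. The libraries differed in depth (macrophages of the NP+ gate had a median of 18286 UMIs, those of control lung 5301), no sort is named for the control lung, and treatment and library cannot be separated. Camp, a granule peptide of neutrophils, was lower in the NP+ gate by 8.71-fold in nonclassical monocytes, 9.57-fold in classical monocytes, 13.15-fold in macrophages and 9.67-fold in alveolar macrophages, but also by 3.245-fold in neutrophils. The neutrophil gene S100a8 was at 2045 against 2130 CPM in classical monocytes, 1251 against 3413 CPM in nonclassical monocytes and 904 against 2190 CPM in macrophages. Other neutrophil genes were lower in each of these classes, in that order: Ngp 5.81, 6.50 and 9.27-fold, Retnlg 4.79, 6.42 and 6.05-fold, and Ltf 5.12, 4.46 and 4.44-fold. The neutrophil marker Il1r2 was 2.04-fold higher in classical monocytes. How far neutrophil RNA differed in these classes was not settled by single genes.

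In neutrophils, Gbp5 (ENSMUSG00000105504), an interferon-induced GTPase, was 65.4-fold higher in the NP+ gate than in control lung (55.8 to 77.1). The chemokines Cxcl10 and Cxcl9, which attract activated T cells, were 68.0-fold (53.9 to 87.1) and 77.2-fold (45.1 to 145) higher, Gbp4 40.1-fold, Gbp8 40.3-fold, Ifi47 35.4-fold, Ifit2 23.1-fold and Igtp 20.5-fold. Of 13 interferon gamma genes 12 were higher (median 3.67), of 15 type I interferon genes 15 (2.53) and of 14 MHC class I genes 14 (2.02, with their transactivator Nlrc5 at 11.5-fold). MHC class II had 2 higher and 3 lower of 13 (0.32), a median that was -0.44 within cluster c12 alone. Cd274, encoding PD-L1, was 20.4-fold higher (18.8 to 22.1). Lower genes included Camp (3.245-fold), Fn1 (5.40-fold) and Epas1 (13.8-fold), the last an abundant endothelial gene.

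The median log2 ratio of all 11305 genes in these neutrophils was -0.24, with 434 higher and 1722 lower. With median-of-ratios size factors 721 were higher and 1173 lower. Neutrophils lay mainly in clusters c3, c2 and c7 of the NP+ gate and c4, c6 and c12 of control lung. The monocyte marker Plac8 (6.83-fold higher) and the macrophage marker Apoe (2.40-fold lower) led the 3 higher and 1 lower genes set aside. NF-kB inflammatory genes had a median of 1.03 with 10 of 17 higher (the adhesion molecule Icam1 6.10-fold), neutrophil maturity genes 0.66 with 5 of 12 higher, chemokines 0.63 with 6 higher and 3 lower of 14, and costimulation 0.77 with 2 higher and 2 lower of 13. The immunosuppressive list had 3 higher and 1 lower of 19 (-0.24), metastatic niche factors 9 of 19 lower (-0.45, the matrix protein Sparc 11.99-fold) and the monocyte-derived dendritic cell list 1 higher and 6 lower of 11 (-0.70, and 0.32 with at least 100 UMIs per gene). Sparc was lower in all 5 myeloid classes of the NP+ gate, by 4.88-fold to 11.99-fold. So were the fibroblast markers Col1a1 and Col3a1, the endothelial markers Egfl7 and Cldn5 and the alveolar marker Sftpc. RNA of such cells in control lung was therefore not separated from the metastatic niche medians of any of these classes. Haemoglobin genes, products of red cells, were higher for 3 of 3 (3.29, Hbb-bs 26.3-fold).

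Nonclassical monocytes of the NP+ gate held 5585 UMIs of Iigp1 (ENSMUSG00000054072), an interferon-induced GTPase, against 0 in control lung, a ratio with a lower limit of 31.3. The serpin Serpina3g was 35.9-fold higher (23.7 to 57.3), the matrix metalloproteinase Mmp14 41.3-fold (14.1 to 200.1), complement factor Cfb 17.7-fold, and Gbp2, Gbp2b, Gbp4 and Gbp5 13.4-fold to 20.9-fold. Fam20a was 12.1-fold lower, the lipid carrier Fabp4 6.39-fold and the transcriptional regulator Id3 3.98-fold. Interferon gamma genes were higher for 11 of 13 (median 3.19), type I for 6 of 15 (0.92), MHC class I for 8 of 14 (1.03) and MHC class II for 5 of 13 with 1 lower (0.92, H2-DMa at 2.79-fold higher). In all 421 genes were higher and 634 lower of 10865, and 4 higher and 13 lower markers of other classes were set aside, led by Ms4a4c (4.09-fold higher) and Camp. NF-kB genes had 3 of 18 higher (0.47), the immunosuppressive list 3 higher and 2 lower of 18 (0.34), the monocyte-derived dendritic cell list 1 of 9 higher (0.32), costimulation 2 higher and 1 lower of 13 (0.11), chemokines 4 of 17 higher (0.70) and metastatic niche factors 7 of 15 lower (-0.71).

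In classical monocytes Iigp1 was 102-fold (51.6 to 237), Gbp4 49.9-fold, Gbp6 28.2-fold, Gbp8 28.0-fold, Cxcl9 25.7-fold, Gbp2b 24.3-fold, Serpina3g 23.7-fold and Gbp2 16.4-fold higher than in control lung. Epas1 was 6.55-fold, the phosphatase Dusp2 2.84-fold and Id3 2.76-fold lower. Interferon gamma genes were higher for 12 of 13 (median 2.82), type I for 12 of 15 (1.54), MHC class I for 10 of 14 (1.14), and MHC class II for 1 with 2 lower of 13 (0.54, H2-Aa 2.24-fold higher). Of 10293 genes 338 were higher and 649 lower (with at least 100 UMIs per gene, 255 and 222), and 3 higher and 7 lower markers were set aside, led by Chil3 (3.13-fold higher) and Camp. NF-kB genes had 7 of 18 higher (0.66, the monocyte chemokine Ccl2 3.12-fold), chemokines 7 higher and 1 lower of 14 (0.89), costimulation 1 higher and 1 lower of 12 (0.11), the immunosuppressive list 2 higher and 1 lower of 17 (0.03), metastatic niche factors 3 of 12 lower (-0.26) and the monocyte-derived dendritic cell list 2 higher and 3 lower of 11 (-0.51).

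In macrophages Iigp1 rose from 1 UMI to 4574, a ratio of 241 (43.3 to 9535), the secreted nuclease Dnase1l3 was 18.3-fold and Gbp2b 18.1-fold higher, Gpnmb 17.5-fold, Cxcl9 13.6-fold, Gbp4 13.3-fold, Serpina3g 12.3-fold and Gbp2 10.3-fold. Retnla showed 3 against 201 UMIs, a ratio of 0.000788 (0.000161 to 0.00234), and Fn1 was 4.07-fold lower. Of the 3 higher and 16 lower markers set aside, Ms4a4c was 2.54-fold higher and the dendritic cell marker Mgl2 52.1-fold lower. Interferon gamma genes were higher for 10 of 13 (median 2.25), type I for 8 of 15 (1.10), MHC class I for 7 of 14 (0.97), and MHC class II had 2 of 13 lower (0.28). Of 10727 genes 425 were higher and 698 lower. NF-kB genes had 7 higher and 1 lower of 18 (0.61, the interleukin 1 receptor antagonist Il1rn 4.64-fold higher), costimulation 1 of 14 higher (0.25, Cd80 2.19-fold), chemokines 4 higher and 5 lower of 18 (0.27) and metastatic niche factors 1 higher and 8 lower of 15 (-1.002). The immunosuppressive list had 3 higher and 6 lower of 19 (0.29), with Cd274 6.54-fold higher and the arginine enzymes Arg1 27.1-fold (14 against 20 UMIs) and Nos2 4.04-fold lower, and the monocyte-derived dendritic cell list 1 higher and 4 lower of 10 (0.06).

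Alveolar macrophages had the lowest interferon gamma median of the 5 myeloid classes, 0.66. Of 13 genes 3 were higher and 1 lower: Gbp5 was 3.89-fold higher, Cxcl10 had a ratio of 5.68 (1.91 to 27.8) over 3 UMIs in control lung, and Cxcl9 was 3.84-fold lower. Type I genes were higher for 4 of 15 (0.58), while MHC class I (0.05) and MHC class II (0.11) had none past the size rule. The keratin Krt79 was 3.31-fold higher (2.65 to 4.18), and the cytokine gene Tnf 2.60-fold, Marcks 3.24-fold and Ccl5, a leading gene of NK cells, 15.2-fold lower. Mitochondrial complex I genes moved both ways, with mt-Nd1 2.75-fold higher and mt-Nd6 3.31-fold lower. Of 10942 genes 110 were higher and 491 lower, with 1 higher and 10 lower markers set aside, led by Plac8 (2.13-fold higher) and Camp. NF-kB genes had 2 of 17 lower (-0.38), the immunosuppressive list 2 of 17 lower (-0.32), metastatic niche factors 4 of 12 lower (-0.71), chemokines 1 higher and 3 lower of 16 (-0.22), costimulation 1 of 10 lower (0.02) and the monocyte-derived dendritic cell list 1 higher and 1 lower of 9 (0.00).

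**Figure D3:**
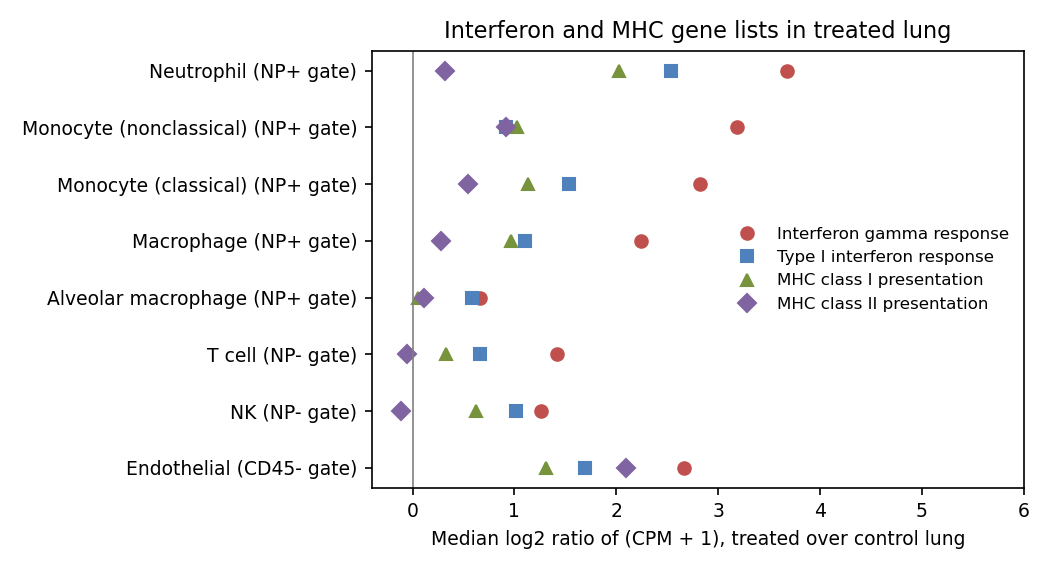
Median log2 ratio of (CPM + 1) of treated over control lung for 4 gene lists in 8 cell classes, with the gate of treated lung in brackets; each point is 1 list in 1 class, from 1 library per group. The interferon gamma median ranged from 0.66 in alveolar macrophages to 3.67 in neutrophils.

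T cells of the NP- gate carried more interferon-inducible RNA than those of control lung. Igtp (ENSMUSG00000078853), an interferon-induced GTPase, was 4.50-fold higher (3.97 to 5.11), Gbp5 4.25-fold, Serpina3g and Iigp1 3.76-fold, Gbp2b 3.63-fold and Irgm2 3.25-fold. The mitochondrial gene mt-Nd1 (3.67-fold) and the actin regulator Arpc4 (3.42-fold) were also higher and mt-Nd6 2.96-fold lower, and these moved the same way in alveolar macrophages against the same control library (Arpc4 2.66-fold higher). Of 13 interferon gamma genes 9 were higher (median 1.42), of 15 type I genes 5 (0.66), and none of 14 MHC class I (0.33) or 13 MHC class II genes (-0.06). Cytotoxic effectors had 4 of 14 higher (0.58, granzyme K gene Gzmk 3.79-fold), checkpoints 3 higher and 1 lower of 11 (0.38) with Pdcd1, encoding PD-1, 2.87-fold higher and Cd160 at a ratio of 8.22 (2.745 to 40.4). Regulatory T cell genes had 2 of 10 higher (0.59), Il10 at 4.56-fold, with Foxp3 at 170.5 against 170.1 CPM, proliferation 3 of 14 (0.52, Mcm2 2.31-fold) and naive and memory genes none of 9 (-0.02). Of 10899 genes 256 were higher and 535 lower (with at least 100 UMIs per gene, 191 and 191), among the latter Epas1 (7.57-fold), Thbd (6.78-fold) and Pltp (5.46-fold). The 3 higher and 7 lower markers set aside were led by Plac8 (3.68-fold higher) and the nonclassical monocyte marker Ace (4.43-fold lower).

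NK cells of the NP- gate had 331 genes higher and 565 lower of 10213, and 283 and 238 with at least 100 UMIs per gene. The near-identical heat shock genes Hspa1a and Hspa1b, whose counts are uncertain for each alone, were 8.24-fold (5.19 to 13.95) and 6.34-fold higher, Gbp2b 5.83-fold, the kinase Pim2 5.20-fold, the activation marker Cd69 3.50-fold and Thy1 3.47-fold. Interferon gamma genes were higher for 7 of 13 (median 1.26, and 1.75 with doublets kept), type I for 9 of 15 (1.01) and MHC class I for 2 of 14 (0.62), and 1 of 13 MHC class II genes was lower (-0.11). Proliferation genes had 7 of 14 higher (0.93, the mitotic genes Ccnb2 4.42-fold and Birc5 2.97-fold), checkpoints 3 of 11 (0.82), cytotoxic effectors none of 13 (0.33, the perforin gene Prf1 at 3275 against 1808 CPM), and dissociation stress genes 2 higher and 3 lower of 14 (-0.30). Of the 1 higher and 15 lower markers set aside, the epithelial gene Sftpc was 135-fold and the endothelial gene Egfl7 58.1-fold lower.

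Endothelial cells of the CD45- gate showed Tgtp1 48.9-fold, Gbp5 32.3-fold (24.4 to 43.8), Igtp 29.5-fold, Iigp1 22.2-fold, the tryptophan-degrading enzyme Ido1 23.2-fold, Gbp6 18.2-fold and Gbp4 15.5-fold above control lung. Ciita, the transactivator of MHC class II, was 15.5-fold higher (12.7 to 19.2) and H2-Ab1 6.97-fold. Interferon gamma genes were higher for 9 and lower for 1 of 13 (median 2.66), type I for 11 and 1 of 15 (1.69), MHC class I for 12 of 14 (1.31) and MHC class II for 8 and 3 of 12 (2.09). Matrix genes had 5 higher and 2 lower of 16 (0.36, and -0.21 at Leiden resolutions 0.5 and 2.0), and endothelial activation genes 1 higher and 4 lower of 15 (-0.05, the angiogenic peptide Apln 4.39-fold lower). Leukocyte genes such as Lyz2 (51.2-fold) and Tyrobp (49.7-fold) were lower in the sorted gate, as were most of the 2 higher and 23 lower markers set aside, led by Ngp (69.8-fold lower). Of 11710 genes 343 were higher and 1126 lower. The cells lay mainly in clusters c1, c17 and c23 of the CD45- gate and c17, c18.3 and c1 of control lung, and within c17 alone the MHC class II median was -0.77.

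The same genes were followed in the comparisons for which no gene was named by size. NP- gate cells set against control lung had interferon gamma medians of 3.46 in neutrophils (12 of 13 higher), 3.19 in nonclassical monocytes (10 of 13), 2.79 in classical monocytes (12 of 13), 2.20 in macrophages (10 of 13), 2.04 in B cells (11 of 13) and 0.95 in alveolar macrophages (6 higher and 1 lower of 11). B cells of the NP- gate held Igtp 6.16-fold (4.68 to 8.29) and Gbp5 5.756-fold above control lung, with most cells in cluster c11 against c15. MHC class II genes were higher for 8 of 13 in NP- nonclassical monocytes (1.14). Pericytes or smooth muscle cells of the CD45- gate had 5 of 11 interferon gamma genes higher (1.13, the median of all genes being 0.14), with Gbp5 at a ratio of 4.11 (1.57 to 15.3). Genes higher and lower numbered 295 and 1617 in neutrophils (median of all genes -0.26), 466 and 541 in nonclassical monocytes, 382 and 688 in classical monocytes, 379 and 564 in macrophages, 204 and 525 in B cells, 141 and 298 in alveolar macrophages and 622 and 633 in pericytes.

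Lymphocytes of the NP+ gate were few, 226 T, 78 NK and 76 B cells, and T and B cells were spread differently over clusters. T cells were mainly in c16 in the NP+ gate (175 cells) and in c14 (875) and c16 (515) in the NP- gate, and B cells in c11 (45) and c15 (31) against c11 (1954) and c15 (135). Against the NP- gate 685 genes were higher and 234 lower in T cells, 287 and 207 in NK cells and 793 and 484 in B cells, whose median over all genes was -0.16. Against control lung the counts were 627 and 439, 278 and 322, and 645 and 723, with a median of -0.14 over all genes in B cells.

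No cluster of carcinoma cells was found in lung, beside 6754 cells of named non-leukocyte classes in the CD45- gate and 893 in control lung. Carcinoma cells were sought as clusters, the smallest lung cluster had 15 cells, and scattered carcinoma cells would not have been counted. The CD45- gate held 80.1% endothelial cells (79.1 to 81.01%), 5.94% pericytes or smooth muscle cells, 5.58% fibroblasts and 1.75% type 1 alveolar cells. Lung fibroblasts were not compared because control lung held 29.

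In primary tumours macrophages made up 11.3% (10.7 to 11.97%, 1096 of 9681 cells) of the NP library and 7.14% (6.75 to 7.55%, 1141 of 15976) of the saline library. This class pooled cluster c5 (699 and 846 cells) with c11 (397 and 295 cells), which scored 2.21 for macrophages and 1.61 for classical monocytes. No tumour cluster was named classical monocyte, so the planned comparison of that class in tumour was not made. T cells made up 43.1% and 43.7%, B cells 16.3% (15.6 to 17.04%) and 13.98% (13.4 to 14.5%), carcinoma cells 8.01% (7.47 to 8.56%) and 10.05% (9.58 to 10.5%), neutrophils 7.22% and 8.27%, and plasma cells 0.413% (0.295 to 0.562%) and 1.04% (0.888 to 1.21%). Unnamed clusters held 10.0% and 12.4%. No sort is named for either tumour.

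**Figure D4:**
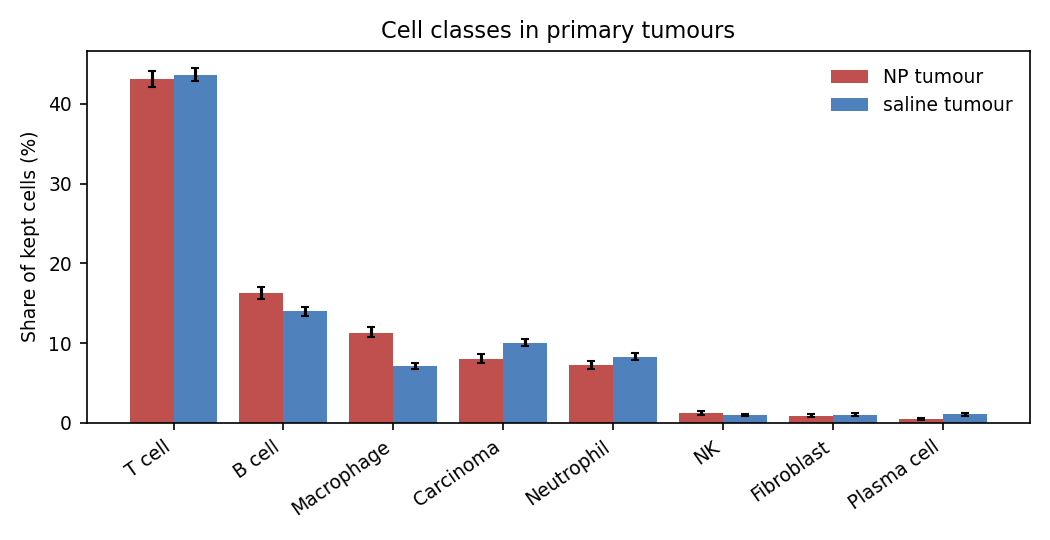
Share of kept cells (%) of 8 cell classes in the NP tumour and the saline tumour, 1 library each; error bars are 95% Clopper-Pearson intervals and cover counting error only. Macrophages reached 11.3% against 7.14%.

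In carcinoma cells of the NP tumour B2m (ENSMUSG00000060802), the light chain of MHC class I, was 2.37-fold higher than in the saline tumour (2.34 to 2.41), Ly6e 2.04-fold and Dynlt1f 2.21-fold, the last belonging to a set of near-identical dynein light chain genes and so uncertain. The immunoglobulin genes Ighg1 (4.79-fold) and Igkc (2.11-fold), products of plasma cells, were lower. B2m was the 1 of 14 MHC class I genes past the size rule (median 0.19). MHC class II (0.37, 13 measured), type I interferon (0.17, 15), interferon gamma (0.21, 14), proliferation (0.19, 14), epithelial-mesenchymal (-0.01, 14) and hypoxia genes (-0.10, 11) had none. Within cluster c10 alone the type I median was -0.08. Of 12611 genes 87 were higher and 142 lower, with each cell weighted equally 136 and 357, and with at least 100 UMIs per gene 20 and 51.

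Tumour macrophages showed higher Saa3 (ENSMUSG00000040026), an acute phase protein (2.53-fold, 2.38 to 2.69), Dynlt1f (2.45-fold) and B2m (2.19-fold), with 72 genes higher and 254 lower of 12016. The markers Chil3 (2.74-fold higher) and Mmp9 (2.08-fold lower) were set aside. Cluster c11, which also scored for classical monocytes, held 397 of 1096 macrophages of the NP tumour and 295 of 1141 of the saline tumour. This shift was not separated from the differences in Chil3 and Mmp9. Acute phase genes had 1 of 12 higher (median 0.38), and chemokines 1 higher and 3 lower of 21 (0.13), with Cxcl13, which attracts B cells, at 301 against 4 UMIs and Ccl17 2.54-fold lower. Metastatic niche factors had 1 higher and 4 lower of 19 (-0.42), Mmp9 and the collagen crosslinking enzyme Lox (2.02-fold) among the lower. The immunosuppressive list had none of 20 (0.08) and the monocyte-derived dendritic cell list 1 higher and 1 lower of 13 (0.02, Cd209a 16.8-fold higher). MHC class I had 1 of 14 higher (0.08), and MHC class II (0.08), type I interferon (-0.05) and interferon gamma genes (0.09) had none past the size rule.

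Tumour neutrophils of the NP library held more of some interferon-inducible genes: Oasl2 (ENSMUSG00000029561) 3.22-fold (2.93 to 3.54), Gbp8 2.98-fold, Gbp4 2.70-fold, Gbp2b and Zbp1 2.49-fold, and B2m 2.67-fold. Type I interferon genes were higher for 7 of 15 (median 0.90), interferon gamma for 2 of 13 (0.61), MHC class I for 1 of 14 (0.39) and MHC class II for none of 13 (-0.16). Granule genes had 2 higher (Chil3 3.15-fold, Fcnb 3.10-fold) and 2 lower of 13 (0.45, Mpo 9.57-fold and Elane 5.08-fold lower), maturity genes none of 12 (0.44) and the immunosuppressive list 1 of 18 lower (0.21). The median of all 10483 genes was -0.35, with 62 higher and 1062 lower. With median-of-ratios size factors 202 were higher and 336 lower, and the MHC class II median was 0.19. Ighg1, Igkc and the T cell genes Trbc1 and Ctla4 were among those lower, and the 3 higher and 12 lower markers set aside were led by Plac8 (2.92-fold higher) and Cd3g (3.93-fold lower). Cluster c7 held 456 of 699 neutrophils of the NP tumour and c9 680 of 1321 of the saline tumour.

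Tumour T cells had 73 genes higher and 174 lower of 12609, with Dynlt1f 2.44-fold and the secreted peroxidase Gpx3 2.32-fold higher and Ighg1 (5.12-fold), Spp1 (2.12-fold) and Fn1 (2.08-fold) lower. Padi4 (2.01-fold) and Wnt7b (2.03-fold), among the leading genes of carcinoma cluster c6, were lower too. Carcinoma cells were 8.01% of the NP and 10.05% of the saline tumour, and RNA of other cells was not separated from these lower genes. The plasma cell marker Jchain (2.55-fold lower) was set aside. Type I interferon genes had a median of -0.37 (percentile 0.00) with none of 15 past the size rule (Ifit3 at 31.3 against 56.6 CPM), interferon gamma -0.06 with 1 of 14 higher, MHC class I -0.02 and MHC class II 0.00 with none. Cytotoxic effectors had 1 of 14 higher (-0.02, the granzyme A gene Gzma 2.54-fold, with Ifng at 15.9 against 19.5 CPM), checkpoints none of 11 (-0.01), regulatory T cell genes 1 of 10 (0.02, Il10 2.41-fold) and naive and memory genes none of 9 (0.06). Cluster c3 held 2099 of 4171 T cells of the NP tumour and c0 3797 of 6977 of the saline tumour.

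Tumour fibroblasts, 87 and 162 cells, showed the kinase Nrk (ENSMUSG00000052854) 7.71-fold (5.79 to 10.4), the opioid precursor Penk 5.36-fold, Serpinb2 4.55-fold, elastin (Eln) 3.99-fold and the basement membrane collagens Col4a1 3.65-fold and Col4a2 3.23-fold higher. Thbs4 (4.44-fold), Tnfrsf9 (4.40-fold) and Spp1 (2.70-fold) were lower, and the neutrophil marker S100a9 (2.14-fold higher) was set aside. Hypoxia genes had a median of -0.69 (percentile 0.00) with 4 of 11 lower, among them Ankrd37 (3.19-fold), the carbonic anhydrase Car9 (2.34-fold) and the growth factor Vegfa (2.03-fold). Matrix genes had 3 of 16 higher (0.11), glycolysis genes none of 13 (-0.17), MHC class I 1 higher and 1 lower of 14 (0.21), MHC class II 1 of 13 lower (-0.35), type I interferon 1 higher and 1 lower of 15 (0.02) and interferon gamma 2 of 13 lower (-0.06). These medians depended on the settings: MHC class II stood at 0.31 and 0.24 at Leiden resolutions 0.5 and 2.0 and at -1.38 with each cell weighted equally, type I at 0.50 with each cell weighted equally, and interferon gamma at 0.32 and 0.29 at those resolutions. Of 11685 genes 169 were higher and 525 lower.

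Tumour B cells had 59 genes higher and 256 lower of 11630, with medians of 0.05 for interferon gamma and -0.19 for type I interferon genes. Tumour NK cells, 116 and 149, had 74 higher and 231 lower of 8660 and 3 of 14 type I genes lower (-0.43), while B2m was 2.205-fold higher in them (1.97 to 2.47).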

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

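The tests of explanations for the liver RNA were chosen after that result was seen. By a rule also written after the medians were seen, gene lists were looked at again where the NP against saline contrast of one class went in opposite directions in lung and tumour, with both medians outside the central 95% of matched random lists. The differences between tissues below were not tested, and the lung and tumour libraries also differ in sort and depth. The lung values come from the NP+ gate for myeloid cells and the NP- gate for lymphocytes.

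The type I interferon list had medians above 0 in lung lymphocytes and below 0 in tumour lymphocytes. The median log2 ratio over saline was 0.66 in lung T cells (5 of 15 members higher) and -0.37 in tumour T cells (0 of 15), a difference of 1.03. In NK cells it was 1.01 (9 of 15 higher) and -0.43 (3 of 14 lower), a difference of 1.44, and in B cells 0.80 (6 of 15 higher) and -0.19 (0 of 15), a difference of 0.99. Proliferation genes of NK cells stood at 0.93 in lung (7 of 14 higher) and -0.68 in tumour (4 of 14 lower), a difference of 1.61.

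In myeloid cells the Nrf2 and iron list of macrophages stood at 0.70 in lung (5 of 14 higher) and -0.15 in tumour (1 of 14 lower), a difference of 0.85. Granule genes of immature neutrophils stood at -1.12 in lung (7 of 13 lower) and 0.45 in tumour (2 higher and 2 lower of 13), a difference of -1.58. The costimulation list of neutrophils stood at 0.77 in lung (2 higher and 2 lower of 13) and -0.05 in tumour (1 lower of 13), a difference of 0.83. Both costimulation medians lay at the top of matched lists (percentiles 100 and 99.09). They were above the medians of all genes in neutrophils, -0.24 in lung and -0.35 in tumour. The list was thus high among matched genes in both tissues, and its change of sign does not show opposite directions.

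A lung cluster left unnamed was led by liver genes, with albumin (Alb) at 21770 CPM and the fibrinogen chain Fgg at 3432 CPM over 223 cells with a median of 891 UMIs. It held 216 cells of the NP+ gate and 7 of the NP- gate, and 0 of 13213 cells in control lung, which allows a share of up to 0.0227%. Of the 216 cells, 207 carried 1 of the 3 probe barcodes of the NP+ gate and 9 another. Albumin in neutrophils followed the same barcode, with 429, 17 and 0 UMIs in the 3 barcodes and a ratio of 22.8 between the highest and the second highest CPM (17.7 against 0.774), which argues against liver RNA spread evenly over the gate. Liver RNA that entered with the material of that 1 probe barcode is consistent with these counts, but the labels do not say what the barcodes stand for, so how it entered stays open and no biological explanation was tested.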

How the results depend on the processing

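Settings within single clusters and the NP tumour's doublet threshold were added after the data were seen, and the other settings were planned. No paired analysis was possible because each group holds 1 library and the groups share only replicate number 1. Of 1759 values of named genes 277 moved beyond their counting interval and 0 changed direction. These genes were picked from the same cells for a ratio of at least 2 or at most 0.5, so a change of direction was unlikely beforehand. Asking for at least 100 UMIs cannot move a gene's ratio. Of 162 counts of genes meeting the size rule 136 lay within 1.5 times the reported count, of 1263 list medians 1218 stayed within their interval and 12 changed sign, and of 150 shares 133 stayed within their interval. Leaving out the filter on cells and using the NP tumour's doublet threshold moved none of these. Except where stated, the cause of a change was not tested. Depth limits the comparisons with control lung, at a median of 2260 UMIs per barcode against 7339 in the NP+ gate, since genes with few UMIs cannot meet the size rule.

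With doublets kept, neutrophils were 51.9% of the NP+ gate and 45.9% of the NP- gate, nonclassical monocytes 21.7% of the NP+ gate and B cells 11.4% of the NP- gate, and interferon gamma medians were 0.07 in alveolar macrophages (NP+ against NP-) and 1.75 in NK cells. At Leiden resolution 0.5 lung macrophages merged with classical monocytes (0 macrophages in each gate, classical monocytes 11.6% and 15.1%), so their comparisons have no value there. T cells were 1.6% of the NP+ gate, carcinoma cells 8.98% of the NP and 11.2% of the saline tumour, and the merged class had 648 genes against NP- and 1534 against control, with medians of 0.28 for MHC class II and -0.02 for type I interferon against NP- and 0.85 for MHC class II against control. Endothelial matrix genes stood at -0.21 and tumour fibroblasts at 0.31 for MHC class II and 0.32 for interferon gamma. At resolution 2.0 B cells were 0.284% and T cells 1.36% of the NP+ gate, T cells 41.9% of the NP and 42.7% of the saline tumour, endothelial matrix genes -0.21, and tumour fibroblasts 0.24 for MHC class II and 0.29 for interferon gamma. Among cells of at least 1000 UMIs T cells were 44.9% and 45.1% of the tumours.

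Asking for at least 100 UMIs leaves fewer genes that can be called. Between the gates it left 67 genes in classical monocytes, 152 in macrophages, 119 in alveolar macrophages, 370 in neutrophils and 93 in nonclassical monocytes. Against control lung it left 477 in classical monocytes, 279 in alveolar macrophages, 1111 in neutrophils, 382 in T cells, 521 in NK cells and 933 in endothelial cells. In tumour it left 71 in carcinoma cells, 93 in macrophages, 441 in neutrophils, 86 in T cells and 282 in fibroblasts. The monocyte-derived dendritic cell median was then 0.02 in macrophages between the gates and 0.32 in neutrophils against control. With each cell weighted equally 299 genes met the rule in alveolar macrophages between the gates, 493 in carcinoma cells and 1095 in tumour fibroblasts, whose MHC class II and type I medians were -1.38 and 0.50. With median-of-ratios size factors tumour neutrophils had 538 genes and medians of 0.19 for MHC class II, 0.74 for MHC class I and 1.25 for type I interferon.

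Within single clusters, lung neutrophils of c6 had 330 genes between the gates and medians of 0.05 for MHC class I, 0.08 for type I and -0.02 for interferon gamma, and those of c12 had 304 genes, 0.08 for MHC class I and 0.09 for interferon gamma. Against control lung c6 had 1006 genes and c12 796, c12 with medians of -0.44 for MHC class II, 1.13 for MHC class I, 1.68 for type I and 1.91 for interferon gamma. Endothelial c17 stood at -0.77 for MHC class II. Carcinoma c6 stood at 0.48 for MHC class II, and c10 at 0.05 for MHC class I, -0.08 for type I and 0.01 for interferon gamma. Tumour macrophage c11 stood at 0.32 for MHC class II, -0.42 for type I and -0.09 for interferon gamma, tumour neutrophil c9 at 0.64 for type I and tumour T cell c8 at -0.15 for MHC class II.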

Other observations

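The tests of explanations in this part, and the genes singled out in it, were chosen after the results were seen. Interferon gamma itself (Ifng) was an NK and T cell transcript among the lung classes looked at. NK cells held it at 447 CPM (383 to 518) in the NP+ gate, 437 CPM (424 to 450) in the NP- gate and 308 CPM (277 to 341) in control lung, and T cells at 173 CPM (148 to 200.4), 62.3 CPM (57.8 to 67.0) and 25.02 CPM (19.1 to 32.2). These T cells lay in different clusters, 175 of 226 in c16 in the NP+ gate but 515 of 1847 in the NP- gate and 266 of 1133 in control lung. Cluster c16 scored 2.21 for T cells and 2.06 for ILC2, and was named through the exception to the runner-up limit. In 1 probe barcode of the NP+ gate T cells were 2.84% of cells, against 0.508% and 0.390% in the others. In the other lung classes looked at with at least 50 cells the highest Ifng value was 5.22 CPM (B cells of the NP- gate). Plasmacytoid dendritic cells, fibroblasts, type 1 alveolar cells and lymphatic endothelial cells were not looked at for Ifng. In tumour NK cells it was 398 CPM (352 to 448) with NP and 661 CPM (609 to 716) with saline. Il12b, a subunit of interleukin 12, which induces interferon gamma, stood at 2824 CPM (2539 to 3131) in the 15 mature dendritic cells of the NP+ gate, 244 CPM (174 to 334) in the 16 of the NP- gate and 10.5 CPM (0.267 to 58.7) in the 96 of control lung. The mature dendritic cells of both gates lay mainly in c22.5 (13 and 15 cells), but 91 of those of control lung lay in c18.1, at a median of 742 UMIs. The CD45- gate held 34 mature dendritic cells, 30 of them in c18.1 as well, which are not among these values.

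Cd274 in alveolar macrophages was at 458 CPM in the NP+ gate, 438 CPM in the NP- gate and 603 CPM in control lung, whereas neutrophils held 704 CPM, 525 CPM and 34.6 CPM. In each of the 5 myeloid classes of the NP+ gate the same 12 genes were higher than in control lung. They were Gbp5, Gbp9, Cxcl10, Ifi47, Igtp, Irgm2, Ifit2, Slfn1, the proteasome subunit Psma7 (2.09 to 2.90-fold), Ube2d3, Kat2b and mt-Nd1. The last was also higher in T cells of the NP- gate against the same control library. A larger set of 78 genes was lower in each of the 5 classes, among them Egfl7, Cldn5, Col1a1, Sftpc and Cd79a, markers of other cell types. These comparisons share 2 libraries, and no chance level was worked out for their agreement.

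Macrophages of the C1qa-rich cluster held Itgax at 444 CPM in the NP+ gate and 471 CPM in the NP- gate, against 126 CPM and 91.2 CPM in the other macrophages. Cxcl9 was at 94.8 CPM (88.0 to 102) and 279 CPM (256 to 303) in that cluster and at 186 CPM and 242 CPM in the others. In tumour, B2m was at 1159 against 489 CPM in carcinoma cells, 970 against 491 CPM in T cells and 297 against 114 CPM in fibroblasts (NP against saline), while the peptide transporter Tap1 was at 377 against 330.1 CPM in carcinoma cells, 473 against 475 CPM in T cells and 390 against 380.2 CPM in macrophages. Dynlt1f was higher in all 7 tumour classes compared, by 2.21-fold to 2.83-fold, and the mast cell protease Mcpt1 lower in all 7. The immunoglobulin gene Ighg1 in T cells was at 125 against 639 CPM, beside plasma cell shares of 0.413% and 1.04%.

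In 4 myeloid classes more genes differed between the gates than between probe barcodes of 1 gate. In neutrophils a median of 734 genes met the size rule over 6 pairs of barcodes from different gates (572 to 825) and 209 over 4 pairs from the same gate (108 to 266). In macrophages the medians were 315.5 (296 to 328) and 124 (91 to 136), in nonclassical monocytes 221.5 (191 to 250) and 87.5 (73 to 99), and in classical monocytes 215.5 (199 to 273) and 98.5 (81 to 131). The labels do not say whether the barcodes of a gate are separate mice or aliquots of a sample, so these counts do not show how far replicate libraries would differ.

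Genes of the interferon gamma list were higher in treated than in control lung in 8 classes other than alveolar macrophages. The tests here used that list alone, and the type I list was not tested. Free RNA of neutrophils does not account for the higher levels in the 7 of these classes that are not neutrophils. The level above control was at least 3.22 times what the neutrophil RNA in them would bring in lymphocytes and endothelial cells (NK cells, with 5.22 in B cells, 6.26 in T cells and 435 in endothelial cells) and at least 14.9 times in classical monocytes, nonclassical monocytes (23.8) and macrophages (30.6). A window of 2000 to 6000 UMIs (lowest interferon gamma median 1.14) left NK cells at 4960 against 2512 UMIs. Equal numbers of cells per library were then drawn in each bin of 500 UMIs. The median over 20 draws was at least 1.76 in 6 classes (T cells, 1.67 to 1.93), which argues against depth in the cells drawn. Only 51 macrophages and 181 nonclassical monocytes per library were drawn, of 1696 and 3998 in the NP+ gate, and deeper cells were not covered. In NK cells the median was 1.04 (0.884 to 1.23). Depth stays open there, as in classical monocytes with 6 such cells in the NP+ gate. Within neutrophil cluster c6 alone the median was 2.67 and within c12 alone 1.91, both below that of all neutrophils. These values argue against a change of neutrophil clusters as the whole cause within c6 and c12. Clusters c2 and c3, with 32 and 24 cells of control lung, had interferon-inducible genes such as Ifit1 and Cxcl10 among their leading genes. A change of clusters is therefore not an explanation separate from the interferon pattern. A response to the particles may underlie the pattern, but handling, the sort and the single library per group were not separated from treatment and stay open.

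Lymphocytes of the NP+ gate held transcripts of nonclassical monocytes, with Cd300e at 145 CPM (118 to 177) in B cells, 50.1 CPM in T cells and 35.5 CPM in NK cells, against 2.996 CPM (2.04 to 4.25), 1.73 CPM and 1.49 CPM in the NP- gate. It was lower in neutrophils (8.85 against 1.48 CPM) and classical monocytes (6.91 against 1.16 CPM), and unnamed clusters with markers of nonclassical monocytes beside those of NK cells (c21.2) or T cells (c21.5 and c21.6) held 55, 40 and 29 cells of the NP+ gate against 3, 0 and 1 of the NP- gate, at medians of 13500, 12270 and 11880 UMIs. If free RNA followed the monocytes' share of UMIs, markers would differ 3.50-fold between the gates, and the highest observed ratio over 3 lymphocyte classes was 0.466 times that with all fixed markers and 1.40 times in B cells without Itgal and Nr4a1, which lymphocytes express. With all markers 86.8% of NP+ and 85.3% of NP- B cells held 5 or more such UMIs, and without those markers 34.2% and 4.98%, the NP+ B cells among them having a median of 12160 UMIs against 4390 in the others. Free RNA and droplets that paired a B cell with a monocyte cannot be told apart here for B cells, since the fixed markers include genes of lymphocytes, the trimmed list was chosen after its values were seen, Cd300e is a single gene, and the unnamed clusters were not tested.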
